A study of Mus musculus with 55 samples.

How the data were processed

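The bulk part of the series holds 48 polyA RNA-seq libraries of mouse liver (strain background C57BL/6, per the labels), in 12 groups of 4 given by genotype and age. The 4 genotypes were Tak1-f/f (floxed Map3k7, the gene of the kinase TAK1, with no deletion named), Tak1-f/f with the Ripk1-D138N allele (a kinase-dead form of RIPK1), Tak1-HEP (the hepatocyte deletion named in the series title) and Tak1-HEP with Ripk1-D138N, called double mutants here. The 3 ages were 4, 6 and 12 weeks. Another 7 samples are single-cell libraries, for which labels were held, and they were not analysed here. The labels number the replicates but do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

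Per the labels' protocols, RNA was extracted with RNAiso Plus and libraries were made with the Vazyme VAHTS mRNA-seq V3 kit. The authors deposited raw counts of read pairs per gene, made per the file headers with featureCounts 1.6.3 over the exons of GENCODE release M 19 (mouse build GRCm38), in pairs and with no strand option. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and genes with near-identical copies (Mup, Cyp2c, Cyp3a, Saa1 and Saa2) are uncertain because reads that match several copies were left out by default. The submitters' processing notes also name STAR, DESeq2, Cell Ranger, Seurat and DESeq, without versions or roles. Trimming, alignment settings and any pooling are not given in the sources used here. The authors also deposited 12 comparison tables with log2 fold changes, and p-values and adjusted p-values stand beside them in the same deposited tables. These were used only to count the authors' calls. Another 24 columns of those tables hold values named by group codes that the labels do not explain, and they were not used.

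The count files hold 54446 genes, of which 54409 were paired with a symbol by the annotation and 37 were not. They hold 0 entries that name no gene. Total counts per library ran from 3923797 to 9214595 (median 7236978), and the 10 most abundant genes took 18.1% to 27.6% of the counts. Of the 72 pairs of replicates within groups, 0 were identical. Chi-square per degree of freedom, over genes with at least 20 counts in the pair, ran from 3.81 to 51.8 (median 13.1), so no library was taken for a copy of another. CPM values used TMM-scaled library sizes, and means are given with the SD over 4 libraries.

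Each age was fitted on its own with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr at its minimum count of 10, a robust quasi-likelihood fit over the 16 libraries of the age with 1 term per genotype, and Benjamini-Hochberg adjustment with calls at an adjusted p under 0.05. The comparisons were Tak1-HEP against Tak1-f/f, double mutants against Tak1-HEP, double mutants against Tak1-f/f, Tak1-f/f Ripk1-D138N against Tak1-f/f, and the interaction, which asks whether D138N acted differently with and without hepatocyte TAK1. Differences between ages came from a fit over all 48 libraries. All adjusted p-values of genes are from this edgeR test unless DESeq2 is named. Map3k7 was also tested as a single value with an exact, 2-sided permutation test on log2(CPM + 1), which cannot give a p below 0.0286 with 4 libraries against 4.

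A set of 31 gene lists with 616 distinct genes (12 to 32 genes each, 43 genes in more than 1 list) was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists and ages for each kind of comparison. The pathway and process lists were NF-kB-driven cytokines and chemokines, interferon-stimulated, acute-phase and complement, cell death, proliferation, extracellular matrix and fibrosis, fetal and liver tumour, NRF2 and oxidative stress, p53 target, unfolded protein response, immediate-early, urea cycle with amino acid and glucose metabolism, cytochrome P450 and xenobiotic, bile acid, fatty acid oxidation, lipogenesis, cholesterol synthesis and sex-biased liver genes, and mitochondrial transcripts. The cell marker lists were recruited macrophage, Kupffer cell, neutrophil, T and NK cell, B and plasma cell, stellate cell, bile duct, endothelial, pericentral and periportal hepatocyte, red blood cell and pancreas markers. Lists with fewer than 3 measured members had no test: pancreas markers at every age, and T and NK cell markers at 12 weeks. Each camera call is given with the adjusted p obtained with an estimated correlation where that loses the call. Counts within a list are over all genes tested, and the count adjusted over the list alone is given beside them.

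The comparisons, lists, filters, tests and the rule for naming genes were fixed before the data were examined. For the comparisons of Tak1-HEP with Tak1-f/f and of double mutants with Tak1-HEP, the rule took the 5 largest rises and 5 largest falls among called genes whose 4 libraries of one group all lay above the 4 of the other, with a mean of at least 1 CPM in the higher group, leaving out unnamed gene models, immunoglobulin and T cell receptor segments and Y-linked genes. It took up to 4 called members of each list by size of change, or the most abundant member where none was called. It always took 13 genes: Map3k7, Ripk1, Ripk3, Mlkl, Casp8, Tnf, Ccl2, Afp, Gpc3, Col1a1, Krt19, Mki67 and Alb. For D138N alone the first part of the rule was used. The values of 1 gene that the rule took are not reported here. Where a group held 0 counts of a gene, the fold is a bound at a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. These intervals and floors cover counting error only.

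The alternatives were DESeq2 1.42.0, RLE size factors, no filter beyond at least 1 count, only the libraries compared, the replicate number as a block, each library left out in turn, Tak1-HEP libraries split between both comparisons that use them, fry and an estimated correlation for the lists, and a pseudocount of 0.5. The 12 leave-one-out fits for the counts of opposite calls used every library of the 3 groups, against 8 as planned. A sex term was planned only if libraries of both sexes occurred, and was not run because all 48 showed the male pattern of Xist and Y-linked genes. Alternatives added after seeing the data were total-count scaling, a batch term at 6 weeks, leaving that batch out, and leaving out pairs of the 12-week double mutants. The batch came from the file headers: replicates 3 and 4 of both 6-week genotypes with intact Tak1 carry alignment numbers used a second time, and their total counts lay between 3923797 and 4379482. Depth entered its definition, since the member of each repeated number with fewer counts was taken as the second batch.

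Replicate numbers were checked for pairing through the correlation of same-numbered libraries' deviations from their group means. Every pair exceeded 0.1 in 1 of 12 comparisons, Tak1-f/f Ripk1-D138N against Tak1-f/f at 6 weeks (r = 0.329, 0.223, 0.15 and 0.339), where replicates 3 and 4 of both groups form the second header batch. The pairing there comes from the values and not from the labels. The test code was checked on simulated counts with 200 genes changed, drawn from the real means and library sizes. For Tak1-HEP against Tak1-f/f, edgeR recovered 73.7% of 2-fold and 93.9% of 4-fold changes at 4 weeks (12133 genes), 66.0% and 94.9% at 6 weeks (12108 genes), and 70.0% and 90.8% at 12 weeks (11842 genes). For the interaction the shares were 46.0% and 88.0% at 4 weeks (12150 genes), 45.0% and 87.0% at 6 weeks (12109 genes) and 31.6% and 85.9% at 12 weeks (11862 genes). Figures were drawn with matplotlib 3.10.9.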

Results

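Liver transcripts were profiled in mice with and without TAK1 in hepatocytes, each with wild-type or kinase-dead RIPK1, at 3 ages. TAK1, encoded by Map3k7, is a kinase that passes signals from cytokine receptors to NF-kB and MAP kinases. RIPK1 is a kinase that can start cell death and inflammation downstream of the TNF receptor, and the D138N allele removes its kinase activity. Each of the 12 groups held 4 libraries. Total counts per library lay between 3923797 and 9214595, and the lowest were those of replicates 3 and 4 of Tak1-f/f at 6 weeks (4379482 and 3923797) and of Tak1-f/f Ripk1-D138N at 6 weeks (4245135 and 4123791). Fold changes are on the log2 scale. Their SE was worked back from the edgeR test, as the absolute log2 change over the square root of its F statistic, and is rough for genes with very few counts in a group. Levels are TMM-scaled CPM with the SD over 4 libraries, and coordinates are on GRCm38.

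Map3k7 itself (ENSMUSG00000028284.13, chromosome 4, 31964097 to 32023467, plus strand) was lower in Tak1-HEP at each age. Counts over the whole gene include exons outside the floxed part and RNA of cells other than hepatocytes, so only a partial fall can show. At 4 weeks the libraries held 57.8, 56.5, 46.7 and 68.9 CPM in Tak1-f/f, 65.0, 61.8, 71.3 and 47.2 in Tak1-f/f Ripk1-D138N, 45.2, 44.3, 46.9 and 34.9 in Tak1-HEP and 44.6, 44.1, 43.1 and 50.4 in double mutants. At 6 weeks they held 43.5, 50.5, 51.5 and 56.97, then 47.95, 42.0, 62.4 and 71.7, then 39.6, 41.2, 39.4 and 39.5, then 39.3, 39.4, 40.1 and 38.4. At 12 weeks they held 59.7, 58.0, 55.7 and 70.2, then 58.5, 63.1, 56.9 and 53.9, then 41.4, 42.6, 43.8 and 47.6, then 48.9, 59.95, 43.9 and 43.1. The library labelled replicate 2 of the 12-week double mutants, at 59.95 CPM, lay within the range of the 12-week Tak1-f/f libraries. At 4 weeks replicate 3 of Tak1-HEP and replicate 4 of the double mutants also lay within the range of Tak1-f/f. Tak1-HEP and Tak1-f/f means were 42.8 ± 5.43 and 57.5 ± 9.09 CPM at 4 weeks (exact permutation p = 0.0571), 39.9 ± 0.842 and 50.6 ± 5.54 at 6 weeks (exact p = 0.0286) and 43.9 ± 2.70 and 60.9 ± 6.39 at 12 weeks (exact p = 0.0286, the smallest possible). In edgeR the change was −0.36 (SE 0.13, adjusted p 0.0227), −0.36 (SE 0.14, adjusted p 0.0465) and −0.46 (SE 0.11, adjusted p 0.00726). The 4-week call was lost without replicate 4 of Tak1-f/f (adjusted p 0.0992) or of Tak1-HEP (0.0805), and the exact p fell to 0.0286 without replicate 3 of Tak1-f/f. The 6-week call was lost without any Tak1-HEP replicate (0.0875, 0.0738, 0.0855 and 0.0950 for replicates 1 to 4) and without replicate 2, 3 or 4 of Tak1-f/f (0.0749, 0.0723 and 0.114). The 6-week exact p was 0.0571 when any 1 Tak1-HEP replicate was left out. The 6-week call was also lost with DESeq2 (adjusted p 0.060), RLE factors (0.0543), no filter (0.0874) and a term for the 6-week header batch (0.210). Under total-count scaling the 4-week change was 0.17, of the opposite sign (adjusted p 0.288), and the 6- and 12-week calls were lost (0.907 and 0.283).

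**Figure D1:**
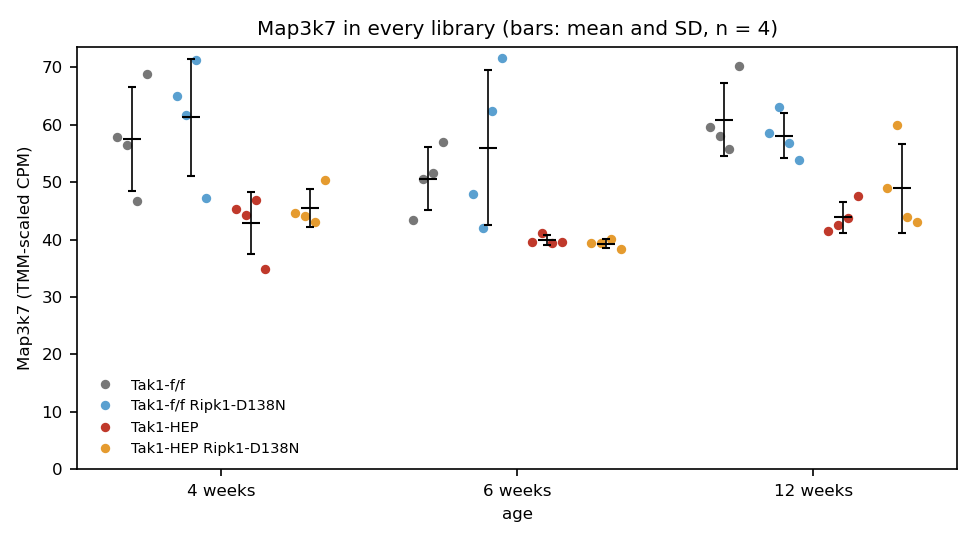
Map3k7 level (vertical axis, TMM-scaled CPM) in each of the 48 libraries by age and genotype, with points for libraries and bars for mean and SD. Tak1-HEP libraries lay between 34.9 and 47.6 CPM, and replicate 2 of the 12-week double mutants stood at 59.95 CPM.

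Tak1-HEP livers were set against Tak1-f/f livers of the same age to ask what loss of TAK1 from hepatocytes changes. Genes of inflammatory signalling and of recruited macrophages rose at every age. Ccl2 (ENSMUSG00000035385.5, chromosome 11, 82035571 to 82037453), a chemokine that attracts monocytes, was 0.540 ± 0.618 CPM in Tak1-f/f and 15.3 ± 6.63 in Tak1-HEP at 4 weeks, and rose by 4.80 (SE 0.60, adjusted p 4.31e-06), 3.87 (SE 0.43, 1.55e-06) and 3.33 (SE 0.65, 0.00112) at 4, 6 and 12 weeks. Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050), the secreted protein osteopontin, rose by 3.65 (SE 0.15, 1.58e-13), 4.86 (SE 0.24, 1.65e-10) and 4.61 (SE 0.32, 3.17e-07), from 41.1 ± 4.38 to 494.7 ± 46.4 CPM at 4 weeks. Among recruited macrophage markers 21 of 21, 22 of 22 and 17 of 19 measured genes rose, as many as when adjusted over the list alone (medians 3.08, 3.25 and 2.47, camera adjusted p 1.02e-33, 1.21e-34 and 1.31e-29). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 7.54 (SE 0.38), 6.05 (SE 0.54) and 4.62 (SE 0.66), and Trem2, a lipid receptor of macrophages, by 5.04 (SE 0.38) at 4 weeks. Mmp12, macrophage elastase, had 1 count over the 4 Tak1-f/f libraries and 2499 over the 4 Tak1-HEP libraries at 4 weeks, a ratio of 1800 (95% counting interval 323 to 71200). Of NF-kB-driven cytokines and chemokines 11 of 15, 13 of 18 and 10 of 16 rose (12, 16 and 10 adjusted over the list alone), with medians of 1.98, 2.33 and 1.37 and camera adjusted p of 6.12e-08, 5.72e-14 and 1.33e-09. They included Cxcl10 (3.88, SE 0.57, 4 weeks), Cx3cl1 (3.02, 3.14 and 3.65) and Lcn2 (4.32, 5.71 and 5.30), whose 12-week call was lost without replicate 1, 3 or 4 of Tak1-f/f (adjusted p 0.0513, 0.0534 and 0.0525). Nfkbia, the NF-kB inhibitor, fell at 4 weeks by 0.30 and was chosen after its values were seen. Tnf was too low to be tested at any age (1.31 ± 1.16 CPM in Tak1-HEP and 0.122 ± 0.159 in Tak1-f/f at 4 weeks).

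Genes of scar matrix, of the stellate cells that make it and of bile duct cells rose as well. Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042), the main fibrillar collagen chain of scar, went from 31.7 ± 6.32 to 184.7 ± 31.4 CPM at 4 weeks, from 10.7 ± 4.01 to 143.8 ± 32.4 at 6 weeks and from 8.33 ± 1.11 to 69.1 ± 14.5 at 12 weeks. These were rises of 2.60 (SE 0.13, adjusted p 7.5e-13), 3.77 (SE 0.27, 3.76e-08) and 3.08 (SE 0.66, 0.00613). Among extracellular matrix and fibrosis genes 28 of 31, 30 of 31 and 26 of 29 rose, as many as when adjusted over the list alone (medians 1.68, 2.75 and 1.98, camera adjusted p 1.4e-28, 4.34e-43 and 2.98e-34), while Fn1, plasma fibronectin made largely by hepatocytes, fell by 0.47 at 4 weeks. Timp1, an inhibitor of matrix proteases, rose by 4.73 (SE 0.58) at 4 weeks, and at 6 and 12 weeks its ratios were 58.0 (19.7 to 283) and 119 (21.0 to 4720). Stellate cell markers rose in 15, 14 and 8 of 20 genes (16, 15 and 9 adjusted over the list alone; medians 1.02, 1.11 and 0.52, camera adjusted p 7.5e-11, 1.67e-09 and 4.6e-05). They included Acta2, the actin of myofibroblasts (2.72, SE 0.32, 4 weeks), Col3a1 (3.26 and 2.48 at 6 and 12 weeks) and Spon2 (2.49, 2.49 and 2.39). Angptl6 fell by 1.36, 1.62 and 1.67 and Ecm1, a regulator of latent TGF-beta made by hepatocytes, by 0.73, 1.36 and 1.36. Bile duct and ductular markers rose in 13 of 18, 17 of 19 and 9 of 17 genes (13, 17 and 13 adjusted over the list alone; medians 1.98, 2.83 and 1.61, camera adjusted p 3.57e-08, 7.78e-17 and 3.31e-13). They included Cldn7 (4.31, SE 0.66 at 4 weeks, but 8.05 without replicate 3 of Tak1-f/f; 3.78, SE 0.44 at 6 weeks; 3.32, SE 0.56 at 12 weeks), a tight junction protein, Prom1 (4.05, 4 weeks) and Krt23 (4.13, 12 weeks). Onecut1, a hepatocyte transcription factor also used in bile duct development, fell by 1.63 and 2.26 at 4 and 6 weeks. Krt19, a bile duct keratin, rose by 1.55 at 6 weeks (SE 0.49, adjusted p 0.0207), a call lost without replicate 2, 3 or 4 of Tak1-f/f (0.0746, 0.0569 and 0.0549), without replicate 2 of Tak1-HEP (0.0917) and with the batch term (0.0747). It was 0.62 (adjusted p 0.260) at 4 weeks and 0.41 (0.730) at 12 weeks. Ecm1 and Onecut1 were chosen after their values were seen.

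Genes of fetal liver and liver tumours, of dividing cells and of oxidative stress rose. Fetal and liver tumour genes rose in 17 of 19, 17 of 20 and 9 of 15 (17, 18 and 10 adjusted over the list alone; medians 2.51, 2.93 and 1.72, camera adjusted p 5.6e-09, 1.7e-14 and 1.46e-08). Ly6d rose by 7.59 (SE 0.50), 7.06 (SE 0.50) and 7.67 (SE 1.08), and H19, an imprinted fetal RNA, by 5.63 (SE 0.76), 10.41 (SE 1.48) and 5.20 (SE 0.74), with a wide spread in Tak1-HEP (965.4 ± 789 CPM at 6 weeks). Afp, alpha-fetoprotein, rose from 2.59 ± 1.42 to 29.3 ± 16.3 CPM at 4 weeks (3.59, adjusted p 5.67e-05) and was 1.24 (0.0556) and 0.25 (0.739) later. Gpc3 rose by 1.11 (0.00656) and 2.25 (0.000386) at 4 and 6 weeks and was 0.37 (0.684) at 12 weeks. Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361), a protein of cycling cells, rose by 1.87 (SE 0.28, 9.56e-05), 2.79 (SE 0.63, 0.00387) and 1.80 (SE 0.38, 0.00274). Of proliferation genes 23, 22 and 3 rose (24, 22 and 3 adjusted over the list alone) of 25, 25 and 22, and Tk1, thymidine kinase, fell by 0.43, 0.63 and 0.91, at 12 weeks in a call lost without replicate 4 of Tak1-f/f (0.0501) or replicate 1 of Tak1-HEP (0.0528). Camera adjusted p were 8.82e-14, 9.91e-11 and 0.00621, against adjusted p = 0.0654, 0.0723 and 0.378 with an estimated correlation. In the list of cell death genes 10, 10 and 5 rose (10, 10 and 8 adjusted over the list alone) of 22, 22 and 20 (camera adjusted p 0.0320, 0.0186 and 0.0156; adjusted p = 0.0810, 0.225 and 0.231 with an estimated correlation). Mlkl (ENSMUSG00000012519.14, chromosome 8), the executioner of necroptosis, rose by 1.93 (SE 0.25, 1.03e-06), 1.06 (0.00103) and 2.02 (0.000345), and Tnfrsf10b, the TRAIL receptor and a p53 target, by 3.42, 3.69 and 2.55.

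Ripk1 did not pass the test (−0.23, 0.16 and −0.26, adjusted p 0.0996, 0.462 and 0.195), and under total-count scaling it rose by 0.29 at 4 weeks (0.0193) and was 0.05 at 12 weeks. Casp8 did not pass either (−0.06, −0.01 and −0.11, adjusted p 0.731, 0.970 and 0.673), and under total-count scaling it was 0.46 (0.00388), 0.32 and 0.19. Ripk3, which activates Mlkl, rose by 1.22 at 4 weeks (0.0470) and 1.51 at 6 weeks (0.0239) from means of 1.48 ± 1.05 and 0.8003 ± 0.452 CPM. These calls were lost without replicates 2 or 3 of Tak1-f/f or 1 or 4 of Tak1-HEP at 4 weeks (0.102, 0.132, 0.172 and 0.0669), and without replicates 2 or 4 of Tak1-f/f or 4 of Tak1-HEP at 6 weeks (0.0640, 0.0631 and 0.0664). Cflar, the inhibitor of Casp8, fell by 0.39 at 4 weeks and Gsdmd rose by 0.34 at 12 weeks, both chosen after their values were seen. Immediate-early genes rose in 11 of 14, 9 of 14 and 5 of 15 (11, 9 and 5 adjusted over the list alone), led by Atf3 (3.96, 4.31 and 2.57), with camera adjusted p of 0.000564, 3.65e-07 and 0.000419 (adjusted p = 0.175 and 0.109 with an estimated correlation at 4 and 12 weeks). NRF2 and oxidative stress genes rose in 11 of 16, 10 of 17 and 7 of 17 (11, 12 and 7 adjusted over the list alone). They included Cbr3 (4.92, 3.67 and 3.01) and Gsta1 at 4 weeks, with 2 counts in Tak1-f/f and a ratio of 469 (130 to 3880). Their camera adjusted p were 0.000937, 0.00014 and 0.000363 (adjusted p = 0.287 and 0.109 with an estimated correlation at 4 and 6 weeks), while Gclm and Ces1g fell at 4 weeks. Of 18 p53 target genes 9, 9 and 8 rose (9, 9 and 10 adjusted over the list alone; camera adjusted p 0.00984, 0.000593 and 7.22e-05; adjusted p = 0.171, 0.0964 and 0.0507 with an estimated correlation). Gclm was chosen after its values were seen.

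Genes of hepatocyte metabolism fell. Alb, serum albumin, fell by 0.64 (adjusted p 6.61e-05), 0.42 (0.00624) and 0.67 (0.0106), calls lost under total-count scaling (0.126, 0.428 and 0.0646) and, at 12 weeks, without replicate 1 of Tak1-HEP (0.0516). The steepest falls included the Mup genes, male-biased urinary proteins with near-identical copies: at 4 weeks Mup15, Mup8 and Mup1 had 0 counts over the 4 Tak1-HEP libraries, at least 122-fold, 45.8-fold and 41.1-fold lower. Hsd3b5, a male-biased steroid enzyme, fell by 9.45 (SE 0.55, 1.92e-08), 7.35 (SE 0.94, 6.97e-05) and 3.87 (SE 0.88, 0.00926), from 223.3 ± 70.4 to 0.311 ± 0.332 CPM at 4 weeks. The 12-week change of Hsd3b5 was −5.84 without replicate 3 of Tak1-HEP. Of sex-biased liver genes 11 of 20, 9 of 19 and 8 of 13 fell (11, 10 and 8 adjusted over the list alone; medians −1.43, −0.67 and −1.13, camera adjusted p 3.4e-05, 0.0319 and 5.93e-06; adjusted p = 0.231 and 0.0629 with an estimated correlation at 6 and 12 weeks). Among the female-biased members Sult2a1 rose at 4 weeks (4.76, but 9.45 without replicate 3 of Tak1-f/f and 3.16 without replicate 4 of Tak1-HEP) and Hao2 at 6 weeks. In the P450 and xenobiotic list 17 of 30, 15 of 30 and 12 of 29 fell (17, 16 and 14 adjusted over the list alone; medians −1.14, −0.77 and −0.94). They included Sult5a1 (−4.93 and −4.50 at 4 and 12 weeks) and Cyp4a12a (−4.18 and −2.65 at 4 and 6 weeks). Its camera adjusted p were 2.16e-06, 0.00035 and 1.24e-05 (adjusted p = 0.0641, 0.201 and 0.119 with an estimated correlation). Of 23 bile acid genes 16, 12 and 9 fell (16, 14 and 11 adjusted over the list alone; camera adjusted p 7.55e-08, 0.000224 and 0.000957; adjusted p = 0.151 with an estimated correlation at 12 weeks). They included Cyp7b1 (−3.41, −4.66 and −2.30) and Cyp8b1 (−2.10, −3.25 and −2.29), enzymes of bile acid synthesis, and Slco1a1, an uptake carrier (−5.39, −3.64 and −2.47). The 12-week call of Cyp7b1 was lost without replicate 2 of Tak1-f/f (0.0502) or replicate 1 of Tak1-HEP (0.0591). The exporter subunit Slc51b rose by 3.31, 3.05 and 3.62.

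Fatty acid oxidation genes fell in 14, 15 and 13 of 22 (16, 17 and 15 adjusted over the list alone; medians −0.55, −0.49 and −0.41). They included Fabp1 (−1.63, −1.54 and −1.01), the fatty acid carrier of liver, and Acsl1 (−1.81 and −1.19 at 4 and 12 weeks), while Pdk4 rose by 1.48, 2.21 and 1.42. Their camera adjusted p were 4.81e-06, 4.77e-05 and 2.34e-06 (adjusted p = 0.247, 0.187 and 0.109 with an estimated correlation). Genes of the urea cycle, amino acids and glucose fell in 21, 14 and 7 of 26 (22, 15 and 9 adjusted over the list alone). They included Tdo2 (−1.65, −1.26 and −0.92). The list had camera adjusted p of 5.65e-11, 3.4e-05 and 0.000593 (adjusted p = 0.0943, 0.211 and 0.311 with an estimated correlation). Lipogenesis genes fell in 16 of 22, 7 of 22 and 2 of 21 (17, 7 and 2 adjusted over the list alone; camera adjusted p 1.3e-06, 0.0730 and 0.435; adjusted p = 0.0728 with an estimated correlation at 4 weeks). Thrsp and Pklr fell at 4 weeks (−3.68 and −2.31), and Cd36, a fatty acid receptor also found on macrophages, rose by 2.24, 2.11 and 1.67. Mitochondrial transcripts fell in 12, 12 and 10 of 13, as many as when adjusted over the list alone (medians −0.89, −0.71 and −0.66, camera adjusted p 3.3e-06, 3.32e-07 and 2.6e-07; adjusted p = 0.129 and 0.153 with an estimated correlation at 4 and 12 weeks). Pericentral markers fell in 12, 11 and 6 of 20 (12, 11 and 8 adjusted over the list alone; camera adjusted p 5.49e-06, 7.08e-06 and 0.00041; adjusted p = 0.109, 0.109 and 0.243 with an estimated correlation), led by Cyp2c29 (−2.05, −1.78 and −1.99). Periportal markers fell in 13, 7 and 4 of 20 (13, 9 and 6 adjusted over the list alone; camera adjusted p 0.00827, 0.0539 and 0.0348; adjusted p = 0.296 and 0.513 with an estimated correlation at 4 and 12 weeks). They included Cyp2f2 (−1.64, −1.31 and −0.98), while Cdh1, E-cadherin, rose by 1.47, 0.93 and 1.16.

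Markers of other cells went different ways. Kupffer cell markers rose in 10 of 17 genes at 4 weeks (10 adjusted over the list alone; camera adjusted p 0.00143, adjusted p = 0.361 with an estimated correlation), led by Marco (1.77), Cd5l (1.62) and C1qc (1.35). At 6 and 12 weeks 8 and 4 rose and 3 and 4 fell (8 and 4, and 4 and 4, adjusted over the list alone; camera adjusted p 0.342 and 0.441), with Cd163, a haemoglobin scavenger receptor of resident macrophages, lower by 3.11 (SE 0.20, adjusted p 2.61e-09) and 4.00 (SE 0.46, 1.16e-05). Neutrophil markers rose in 3 of 4, 5 of 6 and 3 of 4 genes, as many as when adjusted over the list alone (camera adjusted p 0.110, 0.000396 and 0.0187; adjusted p = 0.0964 and 0.211 with an estimated correlation at 6 and 12 weeks). They included S100a8 (2.73, 3.44 and 3.29). B and plasma cell markers rose in 2 of 6, 4 of 9 and 3 of 7 (1, 5 and 3 adjusted over the list alone; camera adjusted p 0.898, 0.0658 and 0.0627), with Igha higher by 1.90 and 1.74 at 6 and 12 weeks. T and NK cell markers had a camera adjusted p of 0.212 and 0.435 at 4 and 6 weeks, and Trbc2 rose by 1.51 at 4 weeks. Of 20 endothelial markers 4, 1 and 1 rose and 7, 4 and 7 fell (4, 1 and 2, and 7, 4 and 8, adjusted over the list alone; camera adjusted p 0.212, 0.329 and 0.00455; adjusted p = 0.214 with an estimated correlation at 12 weeks). Cd34 rose by 1.45, 2.34 and 1.72. The 12-week endothelial median was −0.29, and 0.00427 under total-count scaling. Of the red blood cell markers only Alas2 passed, falling by 2.48, 1.37 and 1.15 (camera adjusted p 0.0223, 0.643 and 0.0186; adjusted p = 0.356 and 0.298 with an estimated correlation at 4 and 12 weeks). Interferon-stimulated genes rose in 11, 5 and 2 of 22 (12, 2 and 2 adjusted over the list alone; camera adjusted p 0.00873, 0.810 and 0.0549; adjusted p = 0.463 with an estimated correlation at 4 weeks), and at 6 weeks their median was −0.03 where the test pointed up. Of 23 acute-phase and complement genes 5 rose and 7 fell at 4 weeks, as many as when adjusted over the list alone, with a median of −0.27 and a mean of 0.37 (camera adjusted p 0.462). At 6 and 12 weeks 12 and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p 0.00278 and 0.0319; adjusted p = 0.305 and 0.624 with an estimated correlation). As lists, cholesterol synthesis (camera adjusted p 0.0906, 0.946 and 0.0510) and unfolded protein response genes (0.212, 0.859 and 0.608) did not pass at any age. Of 23 cholesterol synthesis genes 2, 2 and 1 rose and 8, 0 and 1 fell (2, 0 and 0, and 8, 0 and 1, adjusted over the list alone). Of 20 unfolded protein response genes 1, 1 and 1 rose and 6, 1 and 0 fell, as many as when adjusted over the list alone. Pancreas markers had too few measured members for a test.

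In all, 5847 of 12925 tested genes were called at 4 weeks (3087 higher and 2760 lower, 1799 and 668 of them by 2-fold or more), 4148 of 12999 at 6 weeks (2319 and 1829, 1580 and 463) and 2112 of 12451 at 12 weeks (1175 and 937, 700 and 212). With a term for the header batch at 6 weeks 4963 were called, and 5112 without that batch. The largest rises were Mmp12, Gsta1, Sprr1a, Inava and Krt20 at 4 weeks, H19, Gldn, Shc2, Krt20 and Sprr1a at 6 weeks, and Tmc5, Gldn, Ly6d, Sprr1a and Shc2 at 12 weeks. Sprr1a, an epithelial envelope protein, had ratios of 511 (91.4 to 20200) and 238 (65.5 to 1970) at 4 and 12 weeks and rose by 7.73 (SE 0.87) at 6 weeks. Gldn had ratios of 457 (81.7 to 18100) and 276 (76.2 to 2290) at 6 and 12 weeks, Shc2 of 386 (69.0 to 15300) at 6 weeks and Tmc5 of 524 (93.7 to 20700) at 12 weeks. Inava and Krt20 were at least 39.7-fold and 37.0-fold higher at 4 weeks, each with 0 counts over the 4 Tak1-f/f libraries, and Krt20 at least 30.7-fold at 6 weeks, a call lost with no filter (0.0563) and without the second batch (0.0534). The largest falls were Hsd3b5, Mup15, Mup8, Mup1 and Serpina4-ps1 at 4 weeks, Ppp1r3g and Gtpbp4-ps1 (at least 37.5-fold and 39.8-fold), Mup11, Hsd3b5 and Mup7 at 6 weeks, and Cyp2c53-ps (83.5, 14.5 to 3350), Nat8f7 (52.2, 8.85 to 2110), Sult5a1, Trhde and Cyp2c69 (log2 change −4.20, adjusted p 0.00902) at 12 weeks. Under total-count scaling the median log2 change of all genes was 0.53, 0.32 and 0.29 at 4, 6 and 12 weeks (0.015, −0.027 and −0.012 under TMM), and 90.3%, 88.4% and 90.2% of calls were higher, against 52.8%, 55.9% and 55.6% under TMM. All directions given here are relative to the median under TMM.

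**Figure D2:**
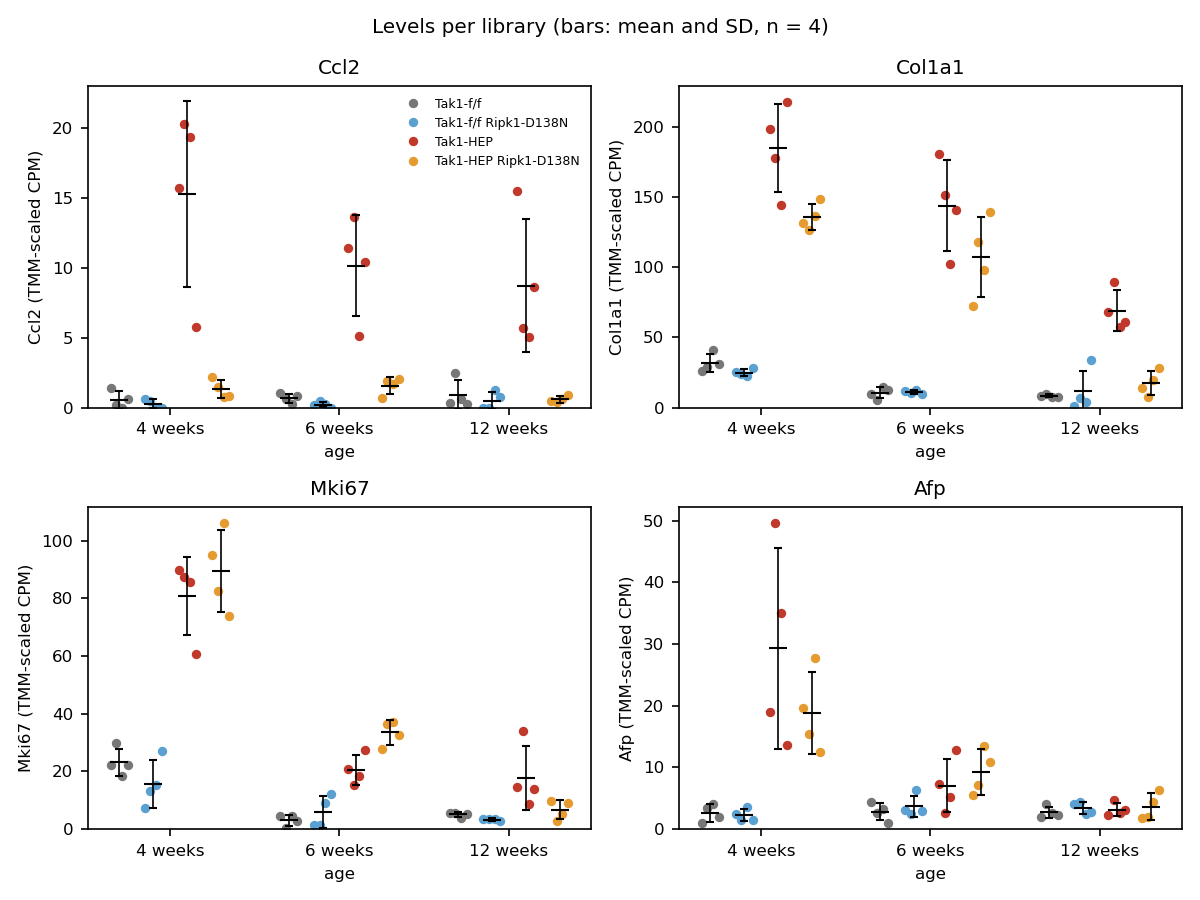
Levels of Ccl2, Col1a1, Mki67 and Afp (vertical axes, TMM-scaled CPM) per library by age and genotype, with points for libraries and bars for mean and SD. Col1a1 stood at 184.7 ± 31.4 CPM in Tak1-HEP and 31.7 ± 6.32 in Tak1-f/f at 4 weeks.

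Double mutants were set against Tak1-HEP to ask what the loss of RIPK1 kinase activity changes where hepatocytes lack TAK1. Several inflammatory genes fell at each age. Ccl2 fell by 3.55 (SE 0.50, adjusted p 0.000244), 2.68 (SE 0.34, 0.000331) and 3.80 (SE 0.67, 0.00135) at 4, 6 and 12 weeks, to 1.32 ± 0.654, 1.57 ± 0.603 and 0.601 ± 0.247 CPM. Cd14, a lipopolysaccharide co-receptor, fell by 2.87 (SE 0.27, 4.14e-07), 2.99 (SE 0.31, 7.21e-05) and 3.36 (SE 0.40, 5.92e-05), and Spp1 by 1.41 (SE 0.14), 1.68 (SE 0.21) and 2.87 (SE 0.29). Of NF-kB-driven cytokines and chemokines 9 of 15, 6 of 18 and 12 of 16 fell (14, 12 and 13 adjusted over the list alone), with medians of −1.22, −0.72 and −1.43 and camera adjusted p of 1.46e-17, 1.73e-18 and 1.56e-12. Cxcl10 fell by 3.33 at 4 weeks, and Cxcl1, a neutrophil chemokine, by 2.25 and 2.31 at 4 and 6 weeks. Cxcl2 was higher in Tak1-HEP at 6 weeks by a ratio of 29.1 (7.74 to 246). Recruited macrophage markers fell in 11 of 21, 3 of 22 and 9 of 19 genes (16, 4 and 12 adjusted over the list alone; camera adjusted p 1.73e-18, 3.69e-05 and 2.58e-15; adjusted p = 0.197 with an estimated correlation at 6 weeks). Ccr2, the receptor for Ccl2, fell by 1.51, 1.59 and 2.14, while Gpnmb did not pass (−0.40, 0.88 and 0.02, adjusted p 0.218, 0.159 and 0.985). Acute-phase and complement genes fell in 6, 15 and 1 of 23 (9, 19 and 0 adjusted over the list alone; camera adjusted p 1.59e-08, 7.74e-34 and 0.203; adjusted p = 0.188 with an estimated correlation at 4 weeks). Saa3, an acute-phase protein, fell by 5.57 (SE 0.40, 1.4e-08) and 4.02 (SE 0.26, 3.61e-08) at 4 and 6 weeks, to 0.429 ± 0.440 and 0.581 ± 0.218 CPM, below the Tak1-f/f means of 4.00 ± 0.303 and 4.62 ± 0.909, and was −1.50 (0.156) at 12 weeks. Saa1 and Saa2, which share sequence, fell by 3.24 and 3.58 at 6 weeks, and the Saa2 call was lost without replicates 1 or 2 of Tak1-HEP (0.0575 and 0.0519) or 1 or 3 of the double mutants (0.0634 and 0.0741).

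Some matrix, ductular and tumour-associated genes fell, and differences between ages were not tested for lists. Extracellular matrix and fibrosis genes fell in 10 of 31, 0 of 31 and 17 of 29 (13, 1 and 25 adjusted over the list alone, with 3 higher at 6 weeks; medians −0.27, −0.10 and −1.17, camera adjusted p 3.49e-06, 0.262 and 1.73e-22; adjusted p = 0.0769 with an estimated correlation at 4 weeks). At 12 weeks Timp1 fell by 3.57 (SE 0.57, adjusted p 0.000307), Col3a1 by 2.02 (SE 0.25, 0.000195) and Postn, a matrix protein of activated fibroblasts, by 1.96 (SE 0.34, 0.000908). Col1a1 fell by 0.48 at 4 weeks (SE 0.12, 0.0129), a call lost without replicate 2 of the double mutants (0.0569), and was −0.44 (0.491) at 6 weeks and −1.99 (0.0625) at 12 weeks, where it was 17.4 ± 8.70 CPM against 69.1 ± 14.5. Ductular markers fell in 7 of 18, 3 of 19 and 6 of 17 (8, 7 and 7 adjusted over the list alone; camera adjusted p 5.16e-05, 0.000538 and 4.04e-08; adjusted p = 0.0681 and 0.197 with an estimated correlation at 4 and 6 weeks). They included Krt23 (−3.65, SE 0.54) and Bicc1 (−1.89, SE 0.23) at 12 weeks. Krt19, Afp and Gpc3 did not pass at any age, Afp at −0.68 (0.320), 0.40 (0.786) and 0.22 (0.792). Fetal and liver tumour genes fell in 5 of 19, 2 of 20 and 5 of 15 (7, 2 and 5 adjusted over the list alone; camera adjusted p 0.000135, 0.955 and 1.19e-05; adjusted p = 0.0503 with an estimated correlation at 4 weeks). They included H19 (−5.04, SE 0.73), Spink1 (−4.05) and Scd2 (−3.63) at 12 weeks and Peg3 and Tff3 (−1.69 and −1.66) at 4 weeks.

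Proliferation and interferon genes went the other way at 6 weeks. As lists, proliferation genes were higher in double mutants at 4 and 6 weeks (medians 0.18 and 0.70, camera adjusted p 0.0102 and 6.99e-17; adjusted p = 0.511 with an estimated correlation at 4 weeks) and lower at 12 weeks (median −1.23, camera adjusted p 4.72e-05; adjusted p = 0.229 with an estimated correlation). Of their members 2, 2 and 0 rose and 0, 0 and 3 fell (2, 8 and 0, and 0, 0 and 6, adjusted over the list alone), led by Rrm2 at 4 weeks (1.17, SE 0.21). Mki67 was 0.10 (0.857) and 0.70 (0.646) at 4 and 6 weeks and fell by 1.38 at 12 weeks (0.0259), a call lost without replicate 2 of Tak1-HEP (−0.87, 0.110) or replicates 2 or 3 of the double mutants (0.0677 and 0.0718). Interferon-stimulated genes were higher as a list at 6 weeks (median 0.51, camera adjusted p 2.46e-16), with 2 of 22 called and 11 adjusted over the list alone, led by Usp18 (1.07, SE 0.16). At 4 and 12 weeks their camera adjusted p were 0.955 and 0.890.

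Some groups of hepatocyte metabolism genes were higher as lists. Among sex-biased genes 7 of 20, 2 of 19 and 7 of 13 rose (10, 6 and 9 adjusted over the list alone; medians 0.82, 0.54 and 0.97, camera adjusted p 8.64e-06, 2.2e-05 and 2.33e-06; adjusted p = 0.0622 with an estimated correlation at 12 weeks). Both male- and female-biased members were among them. Hsd3b5 rose by 4.18 (SE 0.74, adjusted p 0.00369) at 4 weeks, to 5.64 ± 3.96 CPM. The female-biased Cyp3a41a, which has near-identical copies, rose by 6.15 (SE 0.53, 8.7e-06) and 3.77 (SE 0.41, 0.000193) at 4 and 6 weeks, to 45.5 ± 10.7 CPM at 4 weeks against 0.766 ± 1.13 in Tak1-f/f. P450 and xenobiotic genes rose in 5 of 30, 6 of 30 and 10 of 29 (6, 15 and 18 adjusted over the list alone; camera adjusted p 0.000135, 1.01e-15 and 3.51e-10; adjusted p = 0.143 and 0.0505 with an estimated correlation at 4 and 12 weeks). They included Cyp2c29 (1.44) and Sult5a1 (3.91) at 12 weeks. Mitochondrial transcripts rose in 2, 5 and 10 of 13 (4, 7 and 11 adjusted over the list alone; camera adjusted p 0.000921, 1.03e-10 and 3.89e-10; adjusted p = 0.278 and 0.113 with an estimated correlation at 4 and 12 weeks). Fatty acid oxidation genes rose in 8, 2 and 10 of 22 (14, 8 and 18 adjusted over the list alone; camera adjusted p 1.56e-07, 1.13e-05 and 6.45e-10; adjusted p = 0.216, 0.183 and 0.0633 with an estimated correlation). They included Fabp1 (1.04 and 0.83 at 4 and 12 weeks). Slco1a1 rose by 2.90 (SE 0.47) at 4 weeks, and Alb by 0.51 at 6 weeks (0.0210), a call lost without replicates 1, 2 or 4 of Tak1-HEP (0.103, 0.110 and 0.0740) or 1 or 3 of the double mutants (0.0664 and 0.0745). Of 23 bile acid genes 5, 0 and 8 rose and 1, 0 and 1 fell (7, 0 and 9, and 3, 0 and 2, adjusted over the list alone; camera adjusted p 0.0131, 0.0102 and 0.00297; adjusted p = 0.275, 0.158 and 0.197 with an estimated correlation). Of 20 pericentral markers 4, 2 and 11 rose and 1, 0 and 0 fell (4, 8 and 14, and 1, 0 and 0, adjusted over the list alone; camera adjusted p 6.55e-05, 2.06e-08 and 4.14e-12; adjusted p = 0.181, 0.0681 and 0.0505 with an estimated correlation). Lipogenesis genes were higher as a list only at 4 weeks (camera adjusted p 5.37e-07, 0.246 and 0.219; adjusted p = 0.0709 with an estimated correlation at 4 weeks) and periportal markers only at 6 weeks (0.947, 3.49e-06 and 0.376; adjusted p = 0.158 with an estimated correlation at 6 weeks). Urea cycle, amino acid and glucose genes had camera adjusted p of 0.0665, 0.00494 and 0.0388 (adjusted p = 0.431 and 0.608 with an estimated correlation at 6 and 12 weeks), and their 12-week median of 0.15 was −0.091 under total-count scaling.

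In all, 1256, 187 and 1094 genes were called between double mutants and Tak1-HEP at 4, 6 and 12 weeks (617, 67 and 503 higher, 639, 120 and 591 lower; 79, 32 and 117 and 199, 72 and 312 by 2-fold or more). The largest rises were Cyp3a41a, Hsd3b5, Cyp3a44, Cyp3a63-ps and Mup14 at 4 weeks, Cyp3a41a, Hao2, Hhip, Lamc3 and Aqp4 at 6 weeks, and Cyp2c53-ps (48.7, 8.23 to 1970), Mup17, Mup12, Sult5a1 and Mup1 at 12 weeks. The largest falls were Saa3, Scube3, Ankrd1, Ccl2 and Cxcl10 at 4 weeks, Cxcl2, Saa3, Saa2, Saa1 and Cd14 at 6 weeks, and Sybu (81.9, 14.4 to 3270), H19, Vcan, Lmcd1 (30.4, 8.15 to 256) and Rasal1 at 12 weeks. Of these, Mup14 was lost without replicates 2 or 3 of Tak1-HEP (adjusted p 0.0734 and 0.0650) or 1 or 2 of the double mutants (0.0557 and 0.0570), and Mup17 without replicates 1 or 4 of Tak1-HEP (0.0845 and 0.0763) or 1 or 2 of the double mutants (0.0514 and 0.0677). Hao2 was lost without replicates 1, 2 or 4 of Tak1-HEP (0.130, 0.110 and 0.102) or 1, 3 or 4 of the double mutants (0.0630, 0.0553 and 0.102). Hhip was lost without any replicate of Tak1-HEP (0.0803, 0.148, 0.0567 and 0.134) or 1, 3 or 4 of the double mutants (0.0736, 0.0990 and 0.160). The 4-week count was 761, 699 and 834 without replicates 1, 2 and 3 of Tak1-HEP and 743 without replicate 2 of the double mutants. The 6-week count was 73, 78 and 107 without replicates 1, 2 and 4 of Tak1-HEP, 113 and 79 without replicates 1 and 3 of the double mutants, 475 with the batch term and 659 without the second batch. The 12-week count was 648, 715 and 724 without replicates 1, 2 and 4 of Tak1-HEP and 685 without replicate 2 of the double mutants. With total-count scaling the median log2 change of all genes was −0.14, −0.11 and −0.24 (0.0074, −0.019 and 0.00092 under TMM), and 16.6%, 22.3% and 9.31% of calls were higher, against 49.1%, 35.8% and 46.0% under TMM.

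**Figure D3:**
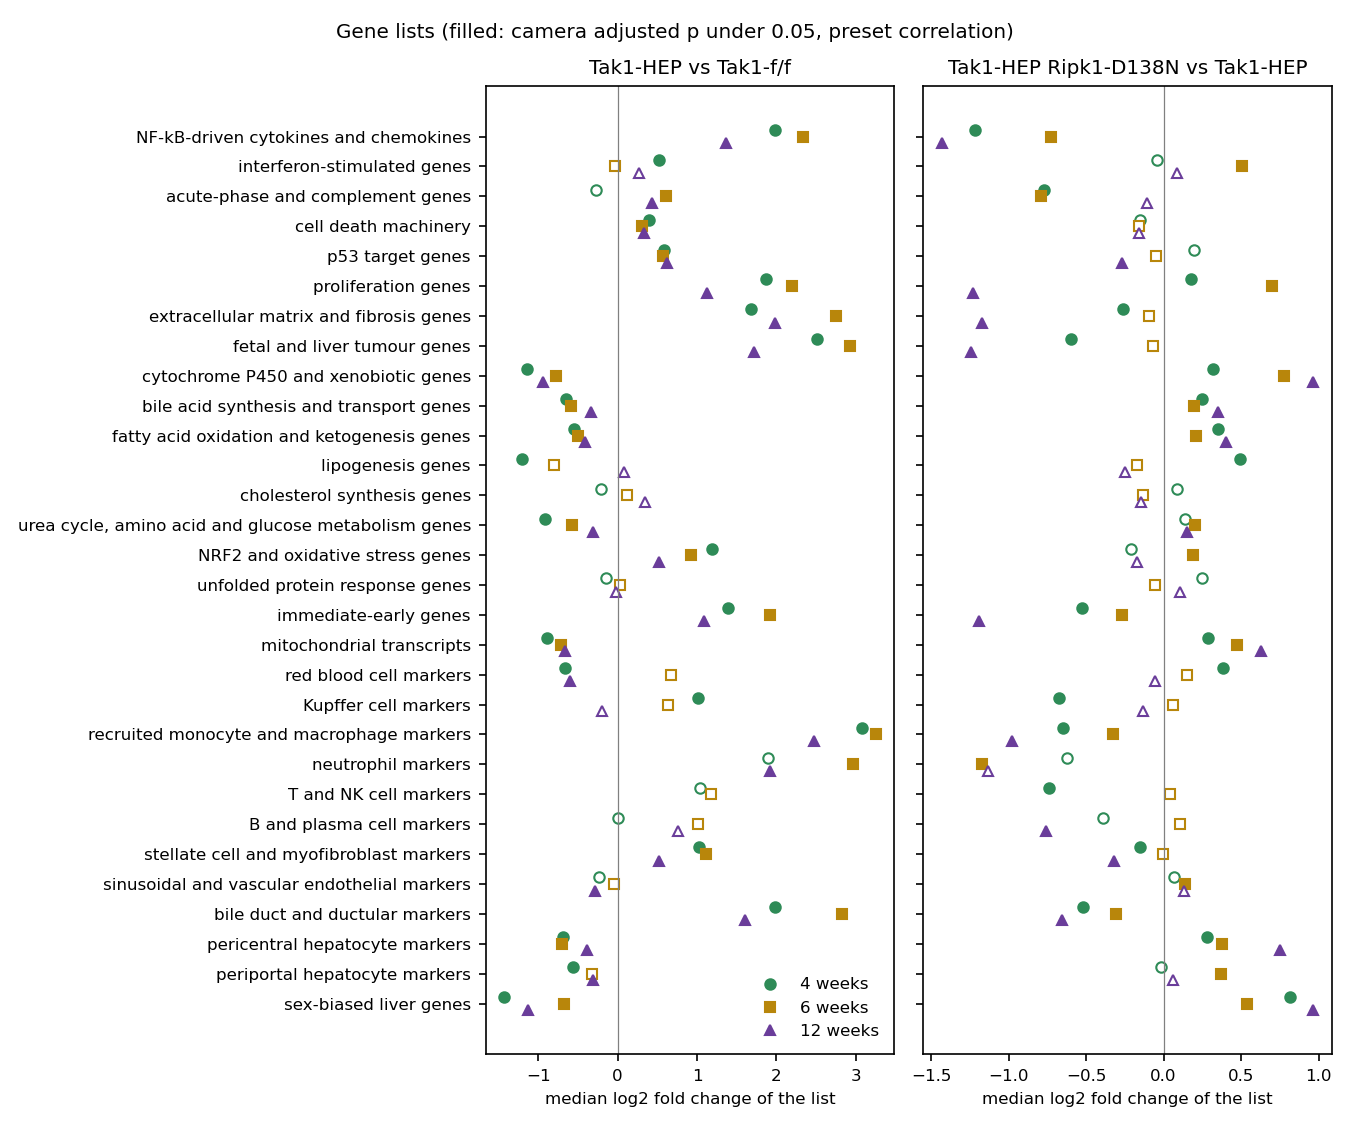
Median log2 fold change (horizontal axis) of each gene list (vertical axis) in Tak1-HEP against Tak1-f/f on the left and double mutants against Tak1-HEP on the right, 1 marker per age, filled where camera's adjusted p at the preset correlation was under 0.05. Recruited macrophage markers stood at 3.08, 3.25 and 2.47 on the left.

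The genes that TAK1 loss and D138N moved in opposite directions numbered 1022 at 4 weeks (553 higher and 469 lower in Tak1-HEP), 119 at 6 weeks (87 and 32) and 864 at 12 weeks (489 and 375), or 17.5%, 2.87% and 40.9% of the genes called for TAK1 loss. Genes called in the same direction in both comparisons numbered 32, 18 and 0. Both comparisons share the Tak1-HEP libraries, which alone can give opposite signs. Simulated counts that kept the effect of TAK1 loss and set double mutants equal to Tak1-HEP gave means of 0, 0.3 and 0.1 genes in 10 runs. Independent lists would share 153 and 132, 21.4 and 9.43, and 55.8 and 37.9 genes, and splitting the Tak1-HEP libraries between the comparisons left 196 or 829, 9 or 51, and 215 or 413 genes. The correlation of fold changes across genes, which are not independent replicates, was −0.562, −0.275 and −0.782 (simulated −0.485, −0.475 and −0.488), and the covariance −0.264, −0.110 and −0.347 (simulated −0.0296, −0.0340 and −0.0407). These simulated correlations and covariances come from other runs with no effect, so lack that of TAK1 loss. Among the opposite calls 528, 53 and 42 were still called in double mutants against Tak1-f/f with the sign of TAK1 loss, 7, 4 and 0 with the other sign, and 487, 62 and 822 were not called. The 4-week count was 645 without replicate 1 of Tak1-HEP, 589 without its replicate 2 and 645 without replicate 2 of the double mutants. At 6 weeks it was 51, 57 and 65 without replicates 1, 2 and 4 of Tak1-HEP, 62 and 59 without replicates 1 and 3 of the double mutants, 283 with the batch term and 386 without the second batch. At 12 weeks it was 529 without replicate 1 of Tak1-HEP and 558 without replicate 2 of the double mutants.

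Double mutants were also set against Tak1-f/f, to see what remained different when both changes were present. Matrix and recruited macrophage genes stayed higher, and at 12 weeks far fewer genes were called. Of extracellular matrix and fibrosis genes 27 of 31, 29 of 31 and 6 of 29 rose at 4, 6 and 12 weeks (29, 29 and 14 adjusted over the list alone; medians 1.41, 2.36 and 0.85, camera adjusted p 8.89e-28, 2.22e-43 and 1.69e-14). Recruited macrophage markers rose in 16 of 21, 19 of 22 and 6 of 19 (18, 20 and 10 adjusted over the list alone; medians 2.10, 2.82 and 1.08, camera adjusted p 2.27e-24, 2.09e-28 and 8.76e-20). Spp1 rose by 2.24 (SE 0.15, adjusted p 2.31e-10), 3.18 (SE 0.22, 1.09e-08) and 1.74 (SE 0.29, 0.00904), and Gpnmb by 7.14 (SE 0.39), 6.93 (SE 0.52) and 4.64 (SE 0.66, 0.00126). Col1a1 rose by 2.12 (5.52e-11) and 3.33 (1.56e-07) and was 1.09 (0.597) at 12 weeks. Ccl2 did not pass (1.25, 1.20 and −0.47, adjusted p 0.214, 0.0828 and 0.887). NF-kB-driven genes rose in 5 of 15, 10 of 18 and 0 of 16 (5, 11 and 1 adjusted over the list alone; camera adjusted p 0.0671, 6.46e-05 and 0.577; adjusted p = 0.131 with an estimated correlation at 6 weeks). With the replicate block the 4-week p was 0.0392. Proliferation genes rose in 24, 23 and 0, as many as when adjusted over the list alone (camera adjusted p 1.67e-26, 6.16e-24 and 0.335), and Mki67 by 1.98 (0.000104) and 3.49 (0.000815) at 4 and 6 weeks. In all 4726, 3956 and 144 genes were called (2530, 2121 and 110 higher, 2196, 1835 and 34 lower), and 4433 and 4335 at 6 weeks with the batch term and without the second batch. At 12 weeks the count was 80 and 66 without replicates 1 and 2 of Tak1-f/f, and 245, 72 and 44 without replicates 2, 3 and 4 of the double mutants. The median log2 change of all genes under total-count scaling was 0.39 and 0.22 at 4 and 6 weeks (0.019 and −0.036 under TMM), and 88.7% and 82.9% of calls were higher, against 53.5% and 53.6%.

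Tak1-HEP and double mutants, each against Tak1-f/f, shared 3878 calls of the same direction at 4 weeks, 3063 at 6 weeks and 127 at 12 weeks. Both comparisons use the Tak1-f/f libraries. Simulated unchanged groups gave 0 shared calls, as a lack of effect nearly ensures. Independent lists would share 604 higher and 469 lower, 378 and 258, and 10.4 and 2.56. Splitting those libraries left 2698 or 2602, 1877 or 1957, and 12 or 47. The correlation of fold changes across genes was 0.893, 0.925 and 0.687 (simulated 0.527, 0.543 and 0.507), and the covariance 0.770, 0.939 and 0.262 (simulated 0.0328, 0.0407 and 0.0425).

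**Figure D4:**
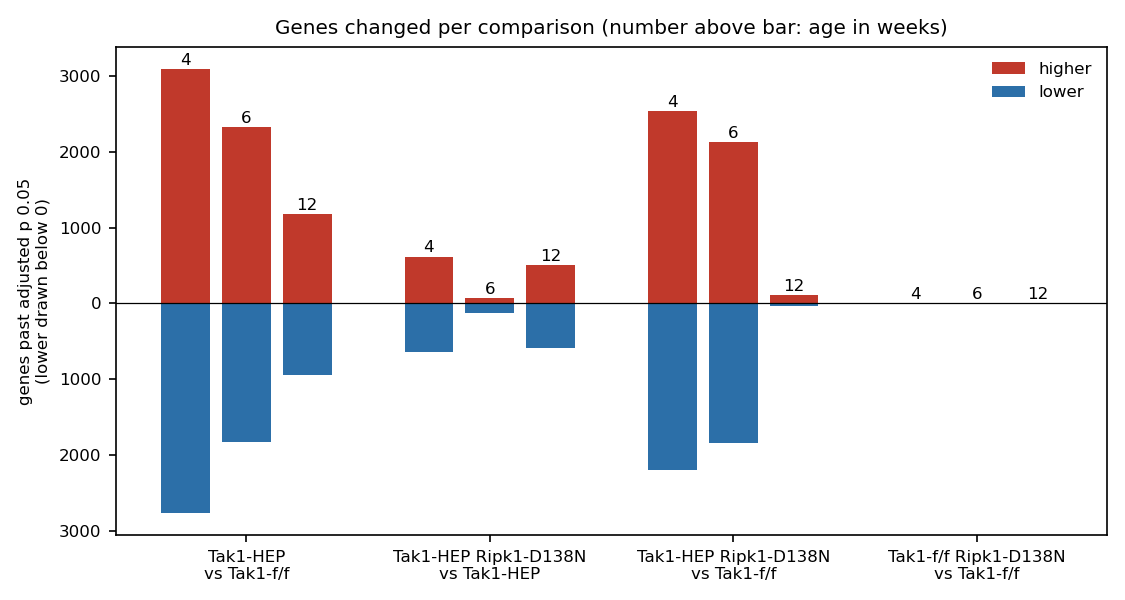
Number of genes past an adjusted p of 0.05 (vertical axis, higher above 0 and lower below 0) for each comparison and age. Tak1-HEP against Tak1-f/f gave 5847, 4148 and 2112 genes and D138N alone gave 1, 0 and 1.

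With hepatocyte TAK1 intact, few transcripts passed the test for the D138N allele, which does not show that few changed. Acot11, an acyl-CoA thioesterase, rose from 2.51 ± 1.34 to 11.1 ± 4.64 CPM at 4 weeks (2.10, SE 0.34, adjusted p 0.0231), and Prox1, a hepatocyte and lymphatic transcription factor, from 90.6 ± 16.7 to 153.7 ± 18.6 CPM at 12 weeks (0.78, SE 0.13, 0.0499). These were the only genes called by edgeR, with 1, 0 and 1 at 4, 6 and 12 weeks, against 14, 0 and 68 by DESeq2. At an unadjusted edgeR p under 0.05 there were 990 of 12925, 533 of 12999 and 1177 of 12451 tested genes. Acot11 was lost without replicates 2 or 3 of Tak1-f/f (0.0699 and 0.0738) or 1 or 2 of Tak1-f/f Ripk1-D138N (0.0779 and 0.130), and with the replicate block (0.0629). Prox1 was lost without replicates 1, 2 or 4 of Tak1-f/f (0.179, 0.158 and 0.0506) or 1, 2 or 3 of Tak1-f/f Ripk1-D138N (0.0712, 0.182 and 0.0536), and with the replicate block (0.0656). The 4-week count was 23 without replicate 4 of Tak1-f/f, 2 and 4 without replicates 3 and 4 of Tak1-f/f Ripk1-D138N, and the 12-week count 4 without replicate 3 of Tak1-f/f. Fatty acid oxidation genes were higher as a list at 12 weeks (median 0.42, 0 of 22 called and 12 adjusted over the list alone, camera adjusted p 1.9e-14, adjusted p = 0.305 with an estimated correlation). At 6 weeks, 0 genes were also called with the batch term, without the second batch and with the replicate block.

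The interaction asked whether D138N acted differently with and without hepatocyte TAK1. Spp1 fell more with D138N where TAK1 was lost, by 1.35 (SE 0.20, adjusted p 0.00157), 2.08 (SE 0.29, 0.00660) and 3.10 (SE 0.40, 0.00137) at 4, 6 and 12 weeks. Cd14 did so by 3.08 (SE 0.44, 0.000756) at 4 weeks, and Saa3 by 4.98 (SE 0.57, 0.000114) and 3.14 (SE 0.37, 0.000811) at 4 and 6 weeks. Hsd3b5 rose more at 4 weeks, by 4.47 (SE 0.81, 0.0196). Ccl2 did not pass (−2.48, −1.22 and −3.05, adjusted p 0.436, 0.853 and 0.193). In all 127, 4 and 290 genes were called (82, 1 and 129 higher; 45, 3 and 161 lower). NF-kB-driven genes were lower as a list at each age (medians −1.27, −0.85 and −1.18, camera adjusted p 1.01e-10, 1.68e-07 and 3.42e-06; adjusted p = 0.0594, 0.0704 and 0.101 with an estimated correlation), with 2, 0 and 2 members called and 8, 5 and 6 adjusted over the list alone. The 4-week count was 63 without replicate 1 of Tak1-f/f Ripk1-D138N and 69, 68 and 385 without replicates 2, 3 and 4 of Tak1-HEP. At 6 weeks it was 10 without replicate 3 of Tak1-HEP, and 2 without its replicate 4, without replicate 1 of Tak1-f/f Ripk1-D138N or without any double mutant, with 11 under the batch term and 109 without the second batch. At 12 weeks it was 190, 182 and 174 without replicates 1, 2 and 3 of Tak1-f/f, 188 without replicate 4 of Tak1-f/f Ripk1-D138N, 153 and 155 without replicates 1 and 4 of Tak1-HEP and 177 without replicate 2 of the double mutants.

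The effect of TAK1 loss was also compared between ages. Of 12147 genes tested at all 3 ages, 1538 were called in the same direction each time (874 higher and 664 lower), where independent lists would share 42.7 and 29.9, and 1 was called at all ages in mixed directions. Against 4 weeks, the effect of TAK1 loss differed in 143 of 13750 genes at 6 weeks and in 506 at 12 weeks. Hsd3b5 had a weaker fall at 12 weeks than at 4 weeks (difference 5.56, SE 1.38, adjusted p 0.0155), and Afp a weaker rise (difference −3.34, adjusted p 0.00326). The effect of D138N in Tak1-HEP differed between 12 and 4 weeks in 100 genes. Spp1 fell more at 12 weeks (difference −1.45, SE 0.31, 0.0118), while the fall of Saa3 was smaller (4.08, SE 0.72, 0.00137). The 6-week count was 73 without replicate 3 of the 4-week Tak1-f/f, 77, 61, 82 and 302 without replicates 1 to 4 of the 4-week Tak1-HEP, 88 and 92 without replicates 1 and 2 of the 6-week Tak1-HEP, 339 with the batch term and 291 without the second batch. The 12-week count was 295 without replicate 2 of the 4-week Tak1-HEP, and the D138N count was 66 and 162 without replicates 2 and 4 of the 12-week double mutants.

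The authors' deposited table of each comparison, read at an adjusted p under 0.05, held 5949, 3953 and 2316 genes for Tak1-HEP against Tak1-f/f at 4, 6 and 12 weeks, of which 5622, 2976 and 2004 were also called here. For double mutants against Tak1-HEP the authors' deposited table held 1502, 542 and 1347 genes (1227, 155 and 1039 shared), for double mutants against Tak1-f/f 4815, 2895 and 290 (4469, 2337 and 136 shared) and for D138N alone 17, 10 and 59 (1, 0 and 1 shared). Of the calls shared with the authors' deposited table, 0 had the opposite sign.

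**Figure D5:**
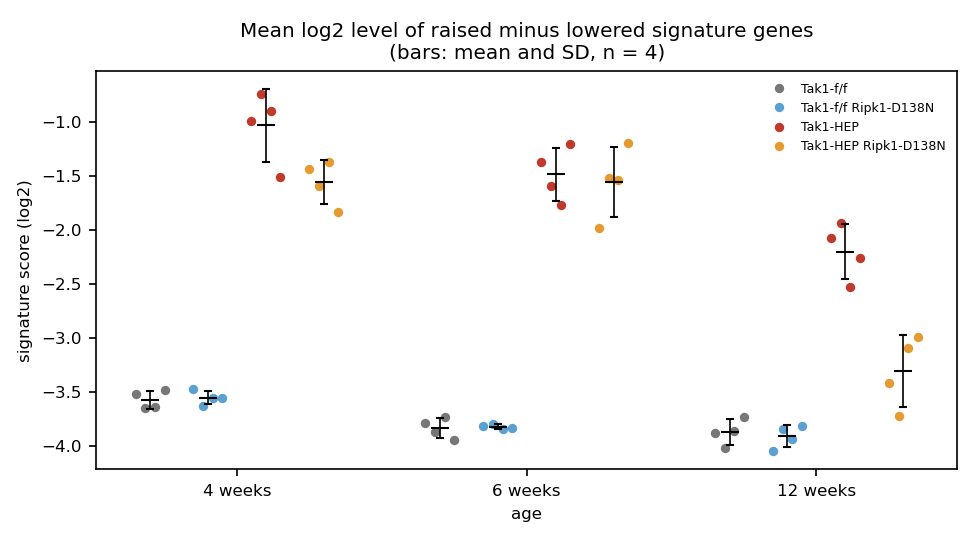
Mean log2 level of raised minus lowered genes (vertical axis) in each library, over 1934 genes called in the same direction in Tak1-HEP and in double mutants against Tak1-f/f at both 4 and 6 weeks. The 12-week double mutants lay between −3.73 and −2.99, the 12-week Tak1-f/f libraries between −4.02 and −3.73 and the 12-week Tak1-HEP libraries between −2.54 and −1.94.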

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

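Tests of spread between 12-week libraries, a 12-week swap, the 6-week batch and the hepatocyte share were chosen only after the result was seen. Those of a smaller 6-week effect and other splits were written before. That of a mislabelled replicate 2 came after the library scores. Among 204 groups of 4 libraries, 15 held a library far from the others, its gap to the nearest one over the range of the group exceeding Dixon's 95% critical value, where chance flags about 1 in 20 groups, or 10.2. At 4 weeks, Mlkl stood at 3.847 CPM in replicate 2 of Tak1-f/f (others 4.103 to 4.149) and Mki67 at 60.85 CPM in replicate 4 of Tak1-HEP (others 85.54 to 89.97). Gpc3 stood at 3.609 CPM in replicate 4 of Tak1-f/f Ripk1-D138N (others 2.898 to 3.005) and at 12.6 CPM in replicate 3 of the double mutants (others 4.752 to 6.025). Alb took 12.644% of counts in replicate 3 of Tak1-f/f Ripk1-D138N (others 11.496% to 11.596%). At 6 weeks, Gpc3 stood at 2.928 CPM in replicate 4 of Tak1-f/f (others 0.6714 to 0.9118). Krt19 stood at 5.035 CPM in replicate 1 of Tak1-f/f (others 1.368 to 1.597) and at 13.73 CPM in replicate 2 of Tak1-HEP (others 4.737 to 5.775). Map3k7 stood at 41.19 CPM in replicate 2 of Tak1-HEP (others 39.42 to 39.61). Mitochondrial transcripts took 9.209% of counts in replicate 3 of Tak1-f/f (others 9.668% to 9.713%) and 8.281% in replicate 3 of Tak1-HEP (others 7.242% to 7.371%). At 12 weeks, Alb took 10.288% of counts in replicate 4 of Tak1-f/f (others 7.48% to 7.768%) and Ccl2 stood at 2.489 CPM in its replicate 2 (others 0.279 to 0.6175). Col1a1 stood at 33.67 CPM in replicate 4 of Tak1-f/f Ripk1-D138N (others 1.366 to 6.579) and Ripk3 at 1.393 CPM in replicate 1 of the double mutants (others 0.5551 to 0.665).

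Of 78 comparisons of whether an always-named gene's effect differed between genotypes or ages, 2 passed. The 78 include interactions that had no test because the gene was too low, Tnf at every age and Ripk3 at 12 weeks. The effect of D138N on Casp8 at 4 weeks was higher by 0.6845 (log2) without hepatocyte TAK1 than with it (adjusted p 0.0465). The effect of TAK1 loss on Afp at 12 weeks was −3.343 (log2) against that at 4 weeks (adjusted p 0.00326).

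The 12-week double mutants lay close to Tak1-f/f, with 144 genes called. Over 1934 genes called in the same direction in Tak1-HEP and in double mutants at 4 and 6 weeks, the median change of double mutants in that direction was 0.95 (quartiles 0.632 and 1.51) at 4 weeks and 0.24 (0.0755 and 0.542) at 12 weeks, a ratio of 0.253, against 0.579 in Tak1-HEP. A wider spread about an unchanged level would hide calls and not shrink the median, so this ratio argues against such spread alone, although choosing genes by their 4- and 6-week calls inflates the 4-week medians. Single libraries near Tak1-f/f would lower the median as well. The signature scores of double-mutant replicates 1 to 4 were −3.421, −3.729, −3.095 and −2.991, so a larger part of the closeness coming from replicates 1 and 2 stays open. Without replicate 2 the 12-week median was 0.30 (0.112 and 0.662) and the ratio 0.316, which argues against a wrong label on that library accounting for the pattern, while whether it is mislabelled stays open. The lowest double-mutant signature score lay 0.001 above the highest Tak1-f/f score (SD of the latter 0.118), so undoing any of the 16 possible swaps of 1 library each could not raise the 12-week difference (0.279 of the 4-week one as labelled, 0.0247 to 0.279 undone), which argues against a swap as the cause of the closeness, while whether one took place and a biological difference with age stay open.

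Few genes were called between double mutants and Tak1-HEP at 6 weeks, 187 against 1256 at 4 weeks. With the second header batch as a term 475 were called, and 659 without that batch, so a wider shared spread from that batch may account for part of the low count. A smaller effect stays open: mean squared log2 change less squared SE (12604 genes) was 0.0717 and 0.146 at 6 and 4 weeks, a ratio of 0.493. Its 95% range over 2000 resamples of genes, which are not independent, was 0.422 to 0.562, including the set bound of 0.5. The batch may widen the 6-week SE (median 0.185, 4-week 0.172) and so lower the ratio.

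Markers of several other cell types were higher in Tak1-HEP. A lower share of hepatocytes, with no change in the state or relative numbers of other cells, would raise the markers of all other types alike. At 6 weeks the median change was 3.25 (quartiles 2.07 and 4.27) over 22 recruited macrophage markers and −0.0413 (−0.427 and 0.114) over 20 endothelial markers. These values are relative to the TMM median, and total-count scaling moved the median of all genes to 0.32. They argue against a lower hepatocyte share as the whole cause. Endothelial markers went both ways, so a lower share together with changes in those cells stays open. A change in number or state of the cell types that rose stays open.

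Chance in how libraries were grouped was checked by counting, among all splits or 100 drawn splits, those with at least as many genes as the real one. For Tak1-HEP against Tak1-f/f, 1 of 35 splits, the real one, reached the real counts of 5847, 4148 and 2112 at 4, 6 and 12 weeks, with highest others of 272, 0 and 10. For double mutants against Tak1-HEP it was 1 of 35 at each age (1256, 187 and 1094, highest others 206, 1 and 1), as it was for the opposite calls (1022, 119 and 864, highest others 201, 1 and 1) and for double mutants against Tak1-f/f (4726, 3956 and 144, highest others 615, 397 and 5). These shares met the rule of fewer than 5 in 100. With 35 splits no smaller share is possible, and no adjustment was made for the number of counts checked. Chance is therefore unlikely for each count taken alone, but not excluded. The interaction at 4 weeks also met the rule, with 3 of 100 splits, although a drawn split gave more genes than the real one (real 127, highest other 300). For the differences between ages 1 of 100 splits each reached the count (real 143, 506 and 100, highest others 4, 90 and 2). Those splits mixed libraries of different ages within a genotype. Any change with age shared by the genotypes then widened their spread and lowered their counts, so they cannot decide about chance. The rule was not met, and chance cannot be excluded, for D138N alone at 4 weeks (7 of 35 splits, real 1, highest other 270) or for the interaction at 6 weeks (6 of 100, real 4, highest other 2612). The 6-week splits took no account of the header batch. The interaction count was 11 with the batch term and 109 without the second batch, and no splits were run for those fits. For D138N alone at 12 weeks 1 of 35 splits reached the real count (real 1, highest other 0), but that 1 gene was lost with the replicate block and under total-count scaling, so no conclusion rests on it. For D138N alone at 6 weeks the real count was 0, which all 35 of 35 splits reach by construction (highest other 3121), so the splits say nothing about chance there. The split with 3121 genes set replicates 1 and 2 of both genotypes against replicates 3 and 4, which is the header batch, and so points to a structure of the samples. With the batch as a term, and without that batch, edgeR called 0 genes for D138N alone at 6 weeks, as did DESeq2 without the term. Without the term 533 of 12999 tested genes had an unadjusted edgeR p under 0.05, below the share of 0.05 that no effect would give.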

How the results depend on the processing

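Total-count scaling, the 6-week batch settings and leaving out pairs of 12-week double mutants were chosen only after the data were seen. Of 597 named gene comparisons, 540 were called, 373 of them under every refit and 403 in every leave-one-out, and 137 were lost in at least 1. Low depth limits calls of genes near the count minimum. Another 8 comparisons of named genes were not tested after the filter, and DESeq2 gave no adjusted p for 4 comparisons. The cause was not tested for any change given here, except where fewer libraries or more genes were tested by construction.

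With DESeq2, D138N alone gave 14 and 68 genes at 4 and 12 weeks, the interaction 337, 45 and 516, double mutants against Tak1-HEP 307 at 6 weeks, double mutants against Tak1-f/f 280 at 12 weeks, the age differences 301 (6 against 4 weeks) and 177 (D138N, 12 against 4 weeks), and opposite calls 179 at 6 weeks. With no filter, D138N alone gave 85 and 183 at 4 and 12 weeks, the interaction 389, 16 and 597, double mutants against Tak1-f/f 413 at 12 weeks, and the age differences 524, 888 and 464. With only the libraries compared, D138N alone gave 0 at 4 weeks, double mutants against Tak1-HEP 616 at 6 weeks and double mutants against Tak1-f/f 75 at 12 weeks. With total-count scaling, D138N alone gave 2 and 0 at 4 and 12 weeks, the interaction 209 and 558 at 4 and 12 weeks, Tak1-HEP against Tak1-f/f 3361, double mutants against Tak1-HEP 1977 and opposite calls 1585 at 12 weeks, the 6 against 4 week difference 240 and calls shared between ages 2412. With the batch term and without the batch, 6-week double mutants against Tak1-HEP gave 475 and 659, the interaction 11 and 109, the 6 against 4 week difference 339 and 291, and opposite calls 283 and 386. Splitting the Tak1-HEP libraries gave 196 opposite calls at 4 weeks, 9 and 51 at 6 weeks and 215 and 413 at 12 weeks. Without pairs 1 and 2, 1 and 3, 1 and 4, 2 and 3, or 2 and 4 of the 12-week double mutants, 333, 477, 664, 383 and 508 genes were called against Tak1-HEP. Against Tak1-f/f 306, 29, 25 and 95 were called without 1 and 2, 1 and 3, 1 and 4, or 2 and 4, and 17 without 3 and 4. Of 245 camera calls 58 held with an estimated correlation, 171 with fry, 244 with RLE factors and 225 with total-count scaling, and 0 changed direction.

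With the replicate number as a block, D138N alone gave 0 genes at 12 weeks, and 242 camera calls were kept, 3 lost and 5 gained. Same-numbered libraries had r from −0.173 to 0.43, with 11 of 48 pairs over 0.1 and 11 libraries closest to their own number. Where the numbers pair the samples, for D138N alone at 6 weeks, the block changed no call.

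Leaving out 1 library at a time, counts at 4, 6 and 12 weeks ranged from 699 to 1683, 73 to 215 and 648 to 1148 for double mutants against Tak1-HEP, and from 44 to 245 against Tak1-f/f at 12 weeks. They ranged from 0 to 23 and 0 to 4 for D138N alone at 4 and 12 weeks, from 63 to 385, 2 to 10 and 153 to 412 for the interaction, and from 589 to 1444, 51 to 158 and 529 to 919 for opposite calls. Age differences ranged from 61 to 302, 295 to 748 and 66 to 162. The log2 difference of Map3k7 ranged from −0.51 to −0.32 and −0.40 to −0.27 at 4 and 6 weeks.

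Signs turned in 41 refits of named genes, 38 of them called in neither fit. In Tak1-HEP against Tak1-f/f, total-count scaling gave Map3k7 0.17, Ripk1 0.29 and Casp8 0.46 at 4 weeks, Casp8 0.32 at 6 weeks, and Ripk1 0.047 and Casp8 0.19 at 12 weeks. At 6 weeks Casp8 was 0.0048 with no filter, 0.27 with the batch term and 0.15 without the batch. Leaving out 1 library gave Casp8 −0.14 to 0.037 and −0.089 to 0.13 at 4 and 6 weeks, and Krt19 −0.48 to 0.74 at 12 weeks. In double mutants against Tak1-HEP, total-count scaling gave Map3k7 −0.11 and Mki67 −0.046 at 4 weeks, Hspa5 −0.094 at 6 weeks (−0.056 with the block), and Map3k7 −0.11, Casp8 −0.066 and Gpc3 −0.013 at 12 weeks. Leaving out 1 library gave Map3k7 −0.037 to 0.093 and Mki67 −0.0091 to 0.19 at 4 weeks. At 6 weeks it gave Hspa5 −0.24 to 0.18, Hbb-bs −0.31 to 0.40, Cd4 −0.34 to 0.051, Igkc −0.10 to 0.55, Mlkl −0.033 to 0.21, Gpc3 −0.36 to 0.15 and Krt19 −0.49 to 0.18. At 12 weeks it gave Scd1 −0.38 to 0.054, Afp −0.22 to 0.46, Gpc3 −0.0078 to 0.47 and Krt19 −0.72 to 0.50.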

Other observations

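The lists in this part were fixed before the data were examined, and Acot11 and Prox1 were looked up in other comparisons only after their result for D138N alone was seen. The library apart on the second principal component was likewise chosen after its value was seen. In the 12-week double mutants several gene groups stayed above Tak1-f/f. Ductular markers rose in 4 of 17 genes (5, and 1 lower, adjusted over the list alone; median 0.92, camera adjusted p 1.68e-07) and fetal and liver tumour genes in 1 of 15 (7, and 1 lower, adjusted over the list alone; median 0.84, camera adjusted p 8.4e-05). NRF2 and oxidative stress genes rose in 2 of 17 (6 adjusted over the list alone; median 0.50, camera adjusted p 5.65e-05). Acot11 rose in double mutants at 4 weeks against Tak1-HEP (1.41, adjusted p 0.00762) and against Tak1-f/f (1.34, adjusted p 0.00351), and Prox1 rose in double mutants against Tak1-f/f at 12 weeks (0.79, adjusted p 0.00285).

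In the interaction, acute-phase and complement genes were lower at 6 weeks (median −0.66, 1 of 23 called and 17 adjusted over the list alone, camera adjusted p 7.52e-19; adjusted p = 0.0594 with an estimated correlation). Interferon-stimulated genes were higher at 6 weeks (median 0.81, 1 of 22 called and 14 adjusted over the list alone, camera adjusted p 1.37e-17; adjusted p = 0.0692 with an estimated correlation). Extracellular matrix and fibrosis genes were lower at 12 weeks (median −0.88, 4 of 29 called and 16 adjusted over the list alone, camera adjusted p 1.41e-11; adjusted p = 0.0692 with an estimated correlation).

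On the second principal component at 12 weeks (7.88% of the variance), replicate 1 of the double mutants lay at 35.01, against 5.716 to 8.519 in the other 3 of its group and −11.04 to 2.5 in the other genotypes. It held counts for 14905 genes, against 15948 to 17757 in the other 3.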
